A study of Rattus norvegicus with 43 samples.

How the data were processed

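The series measures poly(A)-selected mRNA of the kidney cortex of male rats in 43 libraries of 8 groups: SS or SS-Per1-/- (written here as the label Per1KO), on 0.4% or 4% NaCl for 3 weeks, collected at 2pm or 2am. On normal salt there are 6 SS and 6 Per1KO libraries at 2pm, and 6 SS and 5 Per1KO libraries at 2am. On high salt every group has 5. The titles write the 0.4% diet as LS, and it is called normal salt here as in the sample characteristics. No sample was left out, and 0 columns lacked a sample.

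The authors deposited 1 table per diet with FPKM (fragments per kilobase of transcript, scaled to library size) for every gene and library. The deposited unit was checked against the files: FPKM times gene length is a whole multiple of one step per library for 100% of values within 0.01 reads, which recovers whole fragment counts. The submitters' processing notes name fastp, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3. The genome build is not given in the sources used here. The normal salt table lists 32545 genes against 34899 genes on high salt, of which 2354 are loci assembled for that table alone. The tables were made in separate runs, so diet is confounded with table.

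Depth was taken from the recovered fragments. It ran from 24 to 41.6 M fragments per library on normal salt (median 29.7) and from 15.3 to 27.6 M on high salt (median 20.45). The library size behind FPKM was 0.882 to 1.158 times these fragments. On high salt this ratio followed the label. At 2pm it was 1.023 to 1.158 in Per1KO and 0.882 to 0.972 in SS, and at 2am 1.036 to 1.09 and 0.899 to 1.018. The median log2 label difference over all genes was 0.003 at 2pm and -0.007 at 2am. Data were simulated with the group sizes of the 2pm label comparison. Every gene had the same fixed spread, which was not taken from the libraries, so the rates hold for that spread alone. On normal salt limma found 25.4%, 86.6% and 100% of genes changed by 1.5, 2 and 4 fold (7.2% of calls false). On high salt it found 13.4%, 83.6% and 100% (4.4% false). At 1.5 fold most of the simulated changes were therefore missed.

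Values were taken as log2(FPKM + 1). Genes with at least 1 FPKM in at least 5 libraries of a table were tested: 13436 on normal salt, 14899 on high salt and 14102 shared. For each table one model with 4 group means was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, residual spread pooled over the table's groups). The 4 contrasts of label or time and the label by time interaction were read from each fit. Benjamini-Hochberg adjustment ran over all genes of a contrast, and an adjusted p below 0.05 is called passing. All p-values are two-sided. The joint fit of all 43 libraries was used only for interactions with diet, in which a table effect shared by both arms cancels. Diet levels were set side by side without a test, counting genes whose high salt libraries all lay above, or all below, all normal salt libraries.

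A log2 difference is label Per1KO minus SS, or 2am minus 2pm, with its SE from limma. FPKM values are means with SD. An interaction is the difference of 2 such differences. In all 14 contrasts were tested.

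The 38 gene lists for clock, metabolism, transport, injury, immune and cell type genes were fixed in advance. For each list the passing members were counted, also adjusted over the list alone, and camera in limma compared the list with all other genes, at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a contrast. Lists with fewer than 4 tested members were counted but had no camera test. Of 532 pairs of list and contrast, those without a test included, 194 passed at the preset, and 2 with an estimated correlation. Named genes follow a rule written in advance: Per1 and the core clock genes, the 6 largest rises and 6 largest falls with a gene symbol per contrast (5 each way in interactions), up to 4 members with the smallest p per list, and the 8 largest each way for diet. Not all genes that the rule takes are printed, and some are not reported here. Overlaps between contrasts are given with the number that would share a direction if the calls were independent.

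Alternatives chosen in advance were a pseudocount of 0.1, no expression filter, median-ratio rescaling, replicate number as a block, each library left out in turn, a fit of only the groups compared, library number series as a covariate at 2pm on high salt, and separate fits per table for diet interactions. Chosen after seeing the data were voom on the recovered fragments, each library number series of high salt 2pm alone, and leaving out SS high salt 2pm replicates 4 and 5. For each contrast the labels were also exchanged within the groups compared in 99 other ways. Replicate numbers were checked for pairing: libraries of different groups with the same number had a mean residual correlation of 0.02 on normal salt and 0.03 on high salt, so no pairing was used. No 2 libraries of a group were copies (smallest chi-square per gene 9.64 over 95 pairs, 1 being sampling noise alone). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.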

Results

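The kidney cortex of Dahl salt-sensitive (SS) rats and of rats labelled SS-Per1-/- was compared at 2pm, in the inactive phase, and at 2am, in the active phase, on 0.4% NaCl (normal salt) and after 3 weeks on 4% NaCl (high salt). In SS kidneys on normal salt, clock mRNAs swung widely between 2pm and 2am, and in kidneys labelled Per1KO the swing was smaller for the 11 of 18 core clock genes that passed a test of the difference. On high salt, kidneys labelled Per1KO carried lower mRNA for the respiratory chain and the tricarboxylic acid cycle at both times of day. Their mRNA for tubular injury, extracellular matrix and macrophages was higher at both times. When 2pm was fitted by library series, no injury gene and 1 macrophage gene passed in the later of 2 series. Both list medians were positive there (log2 0.40 and 0.52). On normal salt, interferon, macrophage and injury mRNAs were higher in the labelled Per1KO kidneys at 2am, and few genes outside the clock differed at 2pm. Each group holds 5 or 6 rats. Genes were tested with limma, whose p-values weigh a mean difference against the residual spread between libraries, pooled over the groups of a fit. Gene lists were tested with camera.

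Per1 mRNA itself did not differ by label. At 2pm on normal salt the libraries labelled Per1KO held 7.94, 21.9, 15.6, 15.6, 17.2 and 14.6 FPKM of Per1 (mean 15.5, SD 4.51) and the SS libraries 26.9, 16.2, 12.7, 14.1, 15.5 and 18.3 (mean 17.3, SD 5.08). At 2am the values were 14.3, 14.1, 10.9, 9.5 and 11 for the label Per1KO and 8.39, 16.8, 17.3, 8.29, 20.3 and 13.1 for SS. On high salt the libraries labelled Per1KO held 20.9, 13.0, 16.8, 15.5 and 8.64 FPKM at 2pm against 20, 12.7, 8.57, 8.83 and 12.2 in SS, and 10.2, 12.2, 9.76, 11.9 and 9.13 at 2am against 10.9, 11.3, 4.98, 8.85 and 6.21. The log2 differences, label Per1KO minus SS, were -0.16 ± 0.22 (SE; adjusted p = 0.735) at 2pm and -0.16 ± 0.23 (adjusted p = 0.763) at 2am on normal salt, and 0.26 ± 0.24 (adjusted p = 0.446) and 0.35 ± 0.24 (adjusted p = 0.392) on high salt. The mRNA level therefore runs against a reading of the label as loss of the transcript. The labels do not say which part of the gene was altered, and FPKM over the whole gene cannot show a small deletion or a frameshift. Every direction below is drawn from the label Per1KO alone.

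In SS rats on normal salt, the clock genes Nr1d1, Nr1d2 and Dbp fell steeply from 2pm to 2am while Arntl and Cry1 rose. Nr1d1, which encodes the repressor REV-ERB alpha, fell from 35.3 ± 5.65 (SD, n = 6) to 1.86 ± 0.463 FPKM (log2 -3.67 ± 0.11 SE), and Dbp, a clock output transcription factor, fell from 197 ± 53 to 22.3 ± 1.13 FPKM. Nr1d2 (log2 -2.16), Ciart (-1.88) and Per3 (-1.49) fell too, whereas Arntl, which encodes the activator BMAL1, rose from 1.41 ± 0.832 to 17.7 ± 0.884 FPKM (log2 3.02 ± 0.14) and the repressor gene Cry1 rose by log2 2.01. Of 18 core clock genes, 14 changed between the 2 times, 7 of them upward and 7 downward. Per1, at log2 -0.31 ± 0.22 (adjusted p = 0.302), did not pass.

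**Figure D1:**
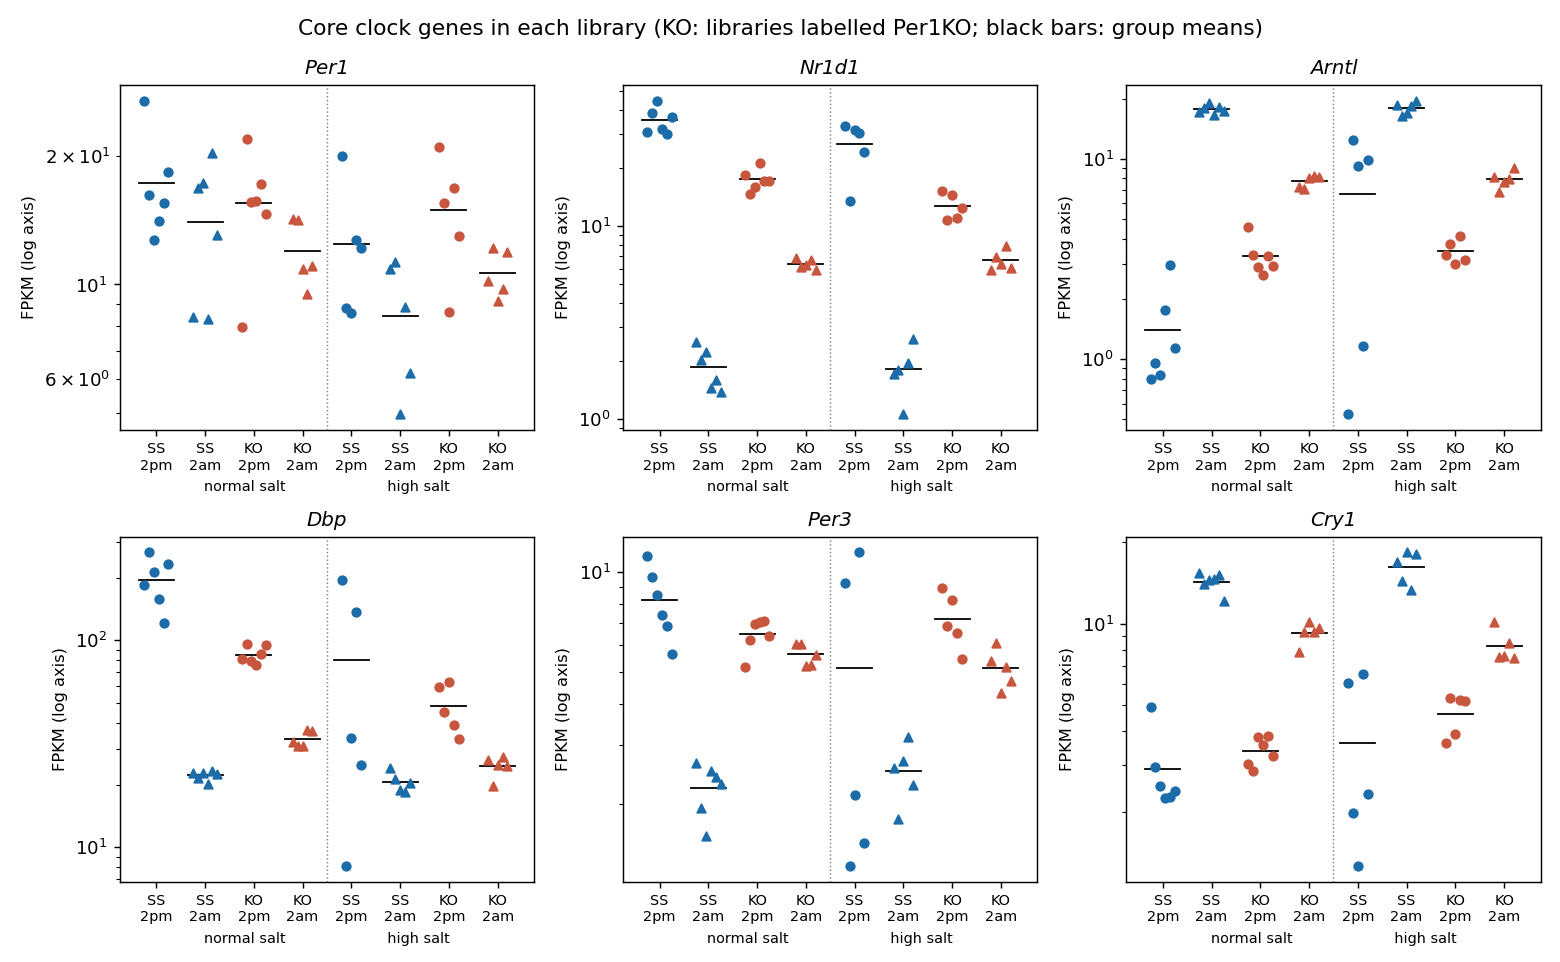
FPKM of 6 core clock genes in each of 43 libraries, on a log axis, by group (SS or label Per1KO, 2pm or 2am, normal or high salt); bars mark group means. Nr1d1 falls from a mean of 35.3 to 1.86 FPKM between 2pm and 2am in SS on normal salt and from 17.4 to 6.35 FPKM in libraries labelled Per1KO, and the 5 SS libraries of high salt 2pm scatter widely in Arntl, Dbp and Per3.

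Beyond the clock, 3534 of 13436 genes changed between 2pm and 2am in SS kidneys on normal salt, 1919 upward at 2am and 1615 downward. The largest rises included Ddit4l2, an inhibitor of mTOR signalling (log2 2.44 ± 0.23), the monocarboxylate transporter Slc16a1 (2.18 ± 0.34), the hypoxia- and stress-responsive gene Ndrg1 (2.03 ± 0.12) and G6pc, which encodes glucose-6-phosphatase (1.66 ± 0.34). In the glucocorticoid response list 6 of 19 rose and 3 fell: Sgk1, the kinase that activates the epithelial sodium channel, rose from 43.4 ± 15.3 to 138 ± 46.7 FPKM, and Tsc22d3 (GILZ) by log2 1.09 ± 0.11. The proximal tubule transport list had 9 of 29 genes up and none down (median log2 0.42; camera adjusted p = 0.000614, and adjusted p = 0.805 with an estimated correlation), led by the urate and phosphate transporter Slc17a3 (1.08 ± 0.08). SS 2pm replicate 5 stood low in proximal tubule markers (given below), and the list was not tested without this library. Fatty acid oxidation and PPAR targets had 8 of 36 up, with the peroxisomal enzyme gene Ehhadh at 0.93 ± 0.13, and the tricarboxylic acid cycle had 8 of 21 up, Ogdh among them (0.66 ± 0.16). Of the cholesterol synthesis and uptake list 7 of 21 rose and 1 fell.

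Chaperone and cold-inducible mRNAs moved with the active phase in SS kidneys. In the heat shock and cold-inducible list 10 of 19 rose and 3 fell (median log2 0.40). Fkbp4, a steroid receptor cochaperone, rose by 0.79 ± 0.08 and the heat shock protein gene Hsph1 by 0.80 ± 0.09, and the cold-inducible Rbm3 fell by 0.90 ± 0.09. Immune and injury mRNAs were lower at 2am. In the interferon response list 17 of 24 fell (20 when adjusted over the list alone; median log2 -0.46; camera adjusted p = 3.48e-08, and adjusted p = 0.805 with an estimated correlation), with the chemokine Cxcl10 at -1.14 ± 0.15 and Isg15 at -0.66 ± 0.11. Macrophages and neutrophils had 11 of 18 lower, with the lysosomal macrophage marker Cd68 at -0.59 ± 0.13, and the tubular injury list 9 of 21, with osteopontin (Spp1) at -1.48 ± 0.30 and the neutrophil gelatinase-associated lipocalin Lcn2 at -1.29 ± 0.30. Cytosolic ribosomal proteins had 16 of 42 lower (25 when adjusted over the list alone), with Rpl3 at -0.43 ± 0.07. All 6 SS libraries of 2pm on normal salt come from one library number series and all 2am libraries from another. The 2pm and 2am libraries of the other groups, on both diets, have separate number ranges too, so the design does not part time of day from library series in the time comparisons or in the tests of damping below. Across these different ranges Nr1d1 was lower at 2am in all 4 pairs of groups (log2 -3.67 and -1.32 on normal salt, -3.24 and -0.84 on high salt, in SS and the label Per1KO), the last not passing. In a fit of only these groups 1785 genes passed.

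In libraries labelled Per1KO on normal salt the time difference had the same sign as in SS for 15 of 18 core clock genes. Nr1d1 fell by log2 1.32 ± 0.11, from 17.4 ± 2.27 (n = 6) to 6.35 ± 0.363 FPKM (n = 5), Dbp by 1.33 ± 0.14, Arntl rose by 1.05 ± 0.15 and Cry1 by 1.23 ± 0.12. Of the 18 genes 7 passed, against 14 in SS, and the median absolute log2 change was 0.27 against 0.98. Across all genes 418 changed, 223 up and 195 down at 2am. The largest falls included Tmem86a, a lysoplasmalogenase gene (-2.04 ± 0.28), Prima1, an anchor of acetylcholinesterase (-1.74 ± 0.27), and Stc1, which encodes a phosphate-regulating hormone (-1.14 ± 0.20). Rises included fatty acid synthase Fasn (1.3 ± 0.32), Csmd1 (1.22 ± 0.16), the vitamin D activating hydroxylase Cyp27b1 (1.04 ± 0.22), the lactate transporter Slc5a8 (1.07 ± 0.20) and the proline dehydrogenase Prodh (0.84 ± 0.11). Fasn did not pass under 9 settings: without the filter, in a fit of only these groups, and without any 1 of 2pm replicates 2, 3, 5 and 6 or 2am replicates 1 to 3.

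Some cholesterol synthesis and protein folding mRNAs rose at 2am in the label Per1KO. Of the cholesterol synthesis and uptake list 5 of 21 rose (8 when adjusted over the list alone; camera adjusted p = 1.45e-06, and adjusted p = 0.0744 with an estimated correlation). In the heat shock list 9 of 19 rose, with Hsph1 at 0.58 ± 0.09 and the endoplasmic reticulum chaperone Hsp90b1 at 0.52 ± 0.09. For sodium transport, the epithelial sodium channel subunit Scnn1a rose by 0.86 ± 0.16 and the sodium pump subunit Atp1b1 by 0.37 ± 0.07, and Cpt1a, the gate of mitochondrial fatty acid entry, fell by 0.64 ± 0.11. None of 24 interferon response, 18 macrophage and neutrophil, 21 tubular injury or 42 ribosomal genes passed, and 1 of 29 proximal tubule transport genes did. The count of 418 ranged from 190 without Per1KO 2am replicate 2 to 601 without Per1KO 2pm replicate 4, and 6 of 11 libraries moved it by over 1.5 times. It was 272 with replicate number as a block and 806 in a fit of only these groups.

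Damping on normal salt was tested directly, within the limit on library series given above. The absolute difference between the times was smaller in the label Per1KO for all 18 core clock genes, for Per1 with a difference of differences of only 0.01 ± 0.32, and for 11 the difference of differences passed, 6 positive and 5 negative (7 and 5 when adjusted over the list alone). Among them were Nr1d1 (log2 2.35 ± 0.15, adjusted p = 4.89e-09), Arntl (-1.97 ± 0.21, adjusted p = 1.33e-05), Dbp (1.72 ± 0.19, adjusted p = 2.09e-05), Ciart (1.60 ± 0.22, adjusted p = 0.000432) and Per3 (1.32, adjusted p = 0.00021). Outside the core clock Slc16a1 (-1.99 ± 0.49), Prima1 (-1.87 ± 0.37) and Sgk1 (-1.61 ± 0.32) differed: Sgk1 stood at 93.3 and 94.6 FPKM at 2pm and 2am in the label Per1KO against 43.4 and 138 in SS. Slc16a1 did not pass under 13 settings: without the filter, and without any 1 of Per1KO 2pm replicates 1, 3 and 6, Per1KO 2am replicates 1 to 4, SS 2pm replicates 2 and 4 or SS 2am replicates 2, 3 and 5. In all 378 of 13436 genes passed. Interferon response genes leaned upward (5 of 24 passing, 19 when adjusted over the list alone; camera adjusted p = 1.85e-11, and adjusted p = 0.473 with an estimated correlation), as did macrophages and neutrophils (6 of 18), and fatty acid oxidation leaned downward (4 of 36). Across genes, the time differences of the 2 genotypes correlated at Pearson r = 0.26 and Spearman rho = 0.22 (13436 genes, which are not independent replicates). The passing genes shared 207 with the same direction and 5 with the opposite, where 55.3 would share a direction by chance. The count of 378 ranged from 127 without Per1KO 2am replicate 2 to 1137 without SS 2pm replicate 3, and 18 of 23 libraries moved it by over 1.5 times. It was 657 with replicate number as a block and 181 without the expression filter.

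At 2pm on normal salt few genes differed by label, 4 core clock genes among them. Nr1d1 was 17.4 ± 2.27 FPKM in the label Per1KO and 35.3 ± 5.65 in SS (log2 -0.98 ± 0.11, adjusted p = 4.62e-05), Dbp was 85.5 ± 8.17 against 197 ± 53, Ciart differed by -1.36 ± 0.15, and Arntl was higher by 0.87 ± 0.14. In the glucocorticoid response list 2 of 19 were higher (5 when adjusted over the list alone), Sgk1 (1.14 ± 0.22) and Tsc22d3 (0.54 ± 0.11). Other higher genes were the lipoprotein lipase inhibitor Angptl4 (1.04 ± 0.21), Prima1 (1.22 ± 0.25), the hedgehog acyltransferase Hhat (0.78 ± 0.13) and Lonrf3 (0.45 ± 0.09). Lower were the EGF receptor ligand Areg (-0.84 ± 0.17), the retinoic acid binding protein gene Crabp1 (-0.74 ± 0.14), Hes6 (-0.61 ± 0.11) and the haem synthesis enzyme gene Alas1 (-0.41 ± 0.09). In all 50 of 13436 genes passed, 34 higher and 16 lower, and 2020 had an unadjusted p under 0.05. By list, core clock had 1 higher and 3 lower of 18 (3 and 7 when adjusted over the list alone) and PAR bZIP and kidney clock output 3 higher and 2 lower of 27. Fatty acid oxidation had 1 of 36 higher (camera adjusted p = 1.86e-06, and adjusted p = 0.976 with an estimated correlation). SS replicate 5 stood low in proximal tubule markers (mean log2 7.85) and high in thick ascending limb markers (6.17), and Per1KO replicate 1 was high in perirenal fat markers (6.29). Leaving out single libraries gave 19 genes (without Per1KO replicate 4) to 110 (without Per1KO replicate 2), beyond 1.5 times for 7 of 12, and a fit of only these groups gave 3, Nr1d1, Dbp and Ciart. Without Per1KO replicate 4 Sgk1, Tsc22d3, Angptl4, Prima1, Lonrf3, Areg, Crabp1 and Alas1 did not pass, and each of these lost its call in 3 to 9 of the 12 leave-one-out fits. The 2 groups also come from different library number series.

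At 2am on normal salt, kidneys labelled Per1KO showed higher injury, interferon, matrix and immune mRNA together with shifted clock genes. Lcn2 stood at 30.7 ± 7.12 FPKM (n = 5) against 11.2 ± 6.36 in SS (n = 6), Spp1 at 1410 ± 391 against 574 ± 297, and Havcr1, which encodes the injury marker KIM-1, at 35.9 ± 12.1 against 13.9 ± 9.68. In the tubular injury list 9 of 21 were higher (11 when adjusted over the list alone; median log2 0.44; camera adjusted p = 1.67e-09, and adjusted p = 0.212 with an estimated correlation), including clusterin Clu (0.86 ± 0.19) and the metalloproteinase inhibitor Timp1 (0.88 ± 0.20). Spp1, Clu and Timp1 did not pass without Per1KO replicate 2 or without Per1KO replicate 3, Timp1 also not without SS replicate 3 or 5, and Havcr1 lost its call under 7 settings: without the filter, and without any 1 of Per1KO replicates 1 to 3 or SS replicates 1, 3 and 5. Of the interferon response list 17 of 24 were higher (21 when adjusted over the list alone; median 0.50; camera adjusted p = 8.19e-20, and adjusted p = 0.181 with an estimated correlation), with the interferon regulator Irf7 (0.82 ± 0.14), Isg15 (0.70 ± 0.12) and the peptide transporter Tap1 (0.55 ± 0.11).

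Immune, matrix and cell cycle genes followed. Macrophages and neutrophils had 9 of 18 higher (14 when adjusted over the list alone; median 0.44), among them complement C1qb (0.80 ± 0.16), Cd68 (0.66 ± 0.14) and Clec10a (0.89 ± 0.18). T and B lymphocytes had 3 of 12 higher, with Cd3e (0.49 ± 0.13) and the B cell chemokine Cxcl13 (0.93 ± 0.23). Extracellular matrix and fibrosis had 5 of 28 higher (22 when adjusted over the list alone; median 0.47; camera adjusted p = 9.03e-13, and adjusted p = 0.212 with an estimated correlation), with collagen Col1a1 (0.87 ± 0.18), the collagen cross-linking oxidase Lox (0.95 ± 0.18), Tgfb1 (0.58 ± 0.13) and Mmp2 (0.56 ± 0.13). Proliferation had 6 of 21 higher (18 when adjusted over the list alone), with Cdk1 (0.59 ± 0.12) and cyclin B1 Ccnb1 (0.53 ± 0.11). Genes on the lower side included Slc17a3 (-0.50 ± 0.08), Ehhadh (-0.55 ± 0.14) and the catalase gene Cat (-0.54 ± 0.13), with 2 of 29 proximal tubule transport genes lower. Without Per1KO replicate 3, Cd68, Clec10a, Col1a1, Tgfb1, Mmp2, Cd3e, Cxcl13, Ehhadh and Cat did not pass, and without Per1KO replicate 2 Tgfb1, Mmp2, Cd3e, Cxcl13, Ehhadh, Cat and Ccnb1 did not. Without SS replicate 3 Tgfb1, Mmp2, Cd3e, Cxcl13, Ehhadh and Cat did not pass, without SS replicate 5 the same genes except Cat, and without SS or Per1KO replicate 1 Cd3e, Cxcl13 and Ehhadh did not. Cd3e did not pass without the filter or with replicate number as a block either. Oxidative phosphorylation had none of 48 past the threshold at a median of -0.21 (camera adjusted p = 4.31e-10, and adjusted p = 0.503 with an estimated correlation).

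Among clock genes at 2am on normal salt, Nr1d1 and Arntl differed in the reverse of their 2pm direction. Nr1d1 was higher by log2 1.37 ± 0.11 and Arntl lower by 1.10 ± 0.15. Nr1d2, higher by 1.28 ± 0.08 (adjusted p = 5.68e-09), and the Clock paralogue Npas2, lower by 0.97 ± 0.14, had not passed at 2pm. Lower too were the carboxylesterase Ces1d (-1.37 ± 0.19), Ddit4l2 (-1.51 ± 0.24), the ubiquitin ligase Rnf125 (-1.32 ± 0.21) and Ppard, a nuclear receptor for fatty acids (-1.04 ± 0.10). In all 561 genes passed, 428 higher and 133 lower. Across genes the label differences at 2am and 2pm correlated at r = -0.20 and rho = -0.24. The count ranged from 91 without Per1KO replicate 3 to 888 without SS replicate 4, beyond 1.5 times for 7 of 11 libraries, and was 2371 (1127 higher, 1244 lower) in a fit of only these groups.

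At 2pm on high salt respiratory chain and tricarboxylic acid cycle mRNAs were lower in kidneys labelled Per1KO and matrix mRNAs higher, in both of 2 library series. Fatty acid oxidation, proximal tubule transport and injury mRNAs differed mainly in the earlier series. Cycs, which encodes cytochrome c, stood at 352 ± 71.9 FPKM (n = 5) against 828 ± 156 in SS (n = 5), and Tgfb1, the central profibrotic cytokine, at 26.6 ± 2.87 against 14 ± 1.99. In nuclear-encoded oxidative phosphorylation 42 of 48 genes were lower and none higher (43 lower when adjusted over the list alone; median log2 -0.49; camera adjusted p = 1.48e-22, and adjusted p = 0.405 with an estimated correlation), with Ndufa4 at -0.83 ± 0.09. In the tricarboxylic acid cycle 17 of 21 were lower (median -0.47), with the succinate dehydrogenase subunit Sdhd (-0.62 ± 0.07) and the pyruvate dehydrogenase subunit Pdhb (-0.76 ± 0.10). Fatty acid oxidation had 9 of 36 lower and 2 higher, with Acadm (-0.73 ± 0.10) and the electron transfer flavoprotein Etfa (-0.62 ± 0.08) lower. Mitochondrially encoded mRNAs had 2 of 11 lower (7 when adjusted over the list alone; median -0.38). Amino acid metabolism had 16 of 34 lower and 2 higher, with the tyrosine-degrading Hgd (-1.01 ± 0.18) and the branched-chain subunit Bckdhb (-0.94 ± 0.14).

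**Figure D2:**
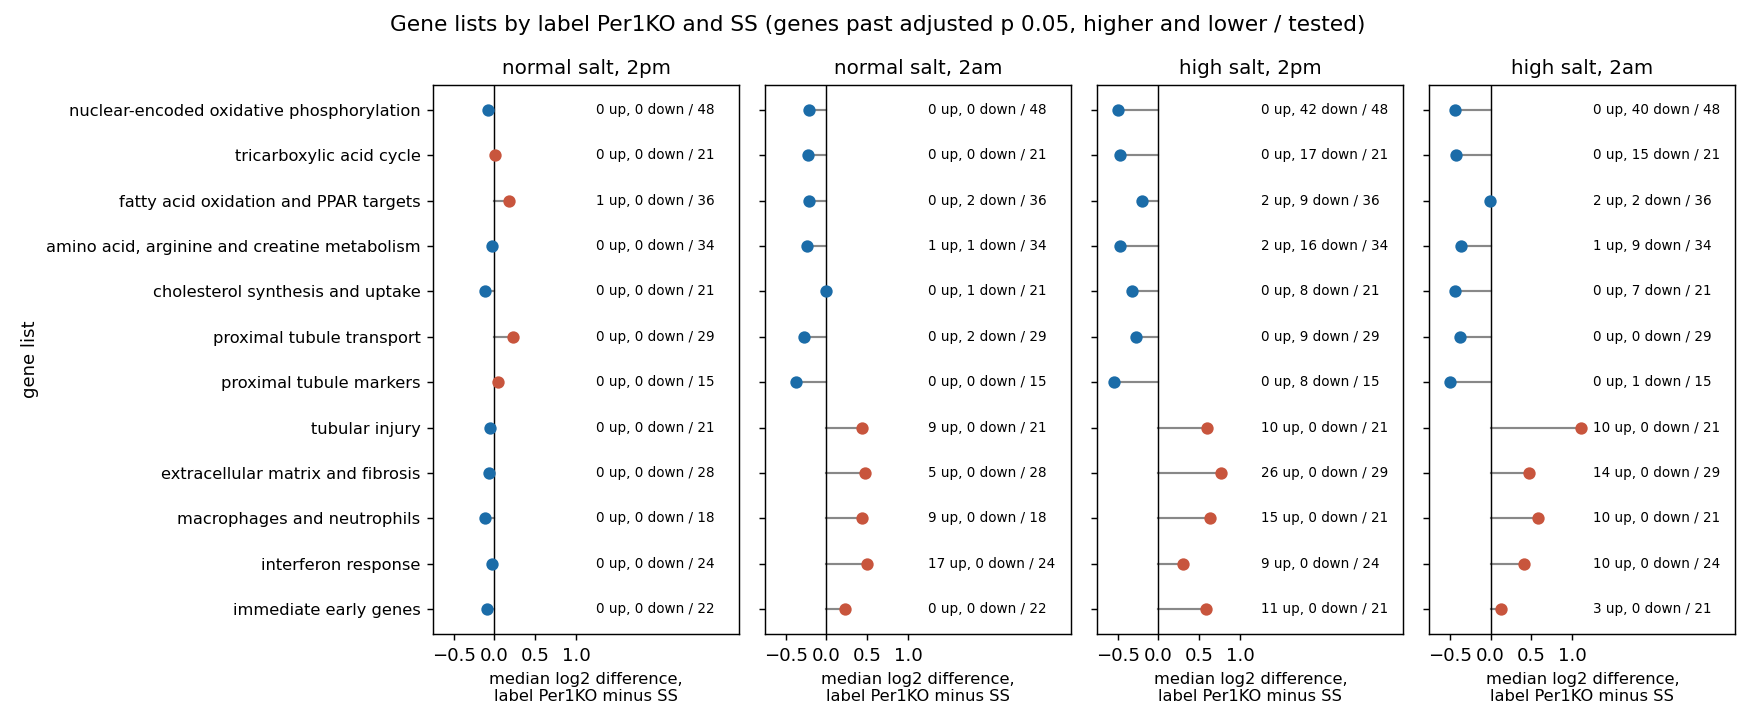
Median log2 difference, label Per1KO minus SS, of 12 gene lists at both times and on both diets, with the number of passing genes higher and lower of those tested printed beside each point. On high salt the oxidative phosphorylation median is -0.49 at 2pm and -0.44 at 2am, and the tubular injury median 0.59 and 1.11.

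Proximal tubule transport had 9 of 29 lower, with the water channel Aqp1 (-1.01 ± 0.15), the urate exporter Abcg2 (-0.81 ± 0.13), the endocytic receptor Lrp2 (-0.85 ± 0.19) and the cystine transporter subunit Slc3a1 (-1.38 ± 0.31). Among the largest falls across all genes were the amino acid transporters Slc7a12 (-2.89 ± 0.89) and Slc7a13 (-2.73 ± 0.91), Cyp2c11 (-2.75 ± 0.65) and regucalcin Rgn (-2.41 ± 0.59), the glutathione transferase Gsta5 also being lower (-1.04 ± 0.16). Proximal tubule markers had 8 of 15 lower (median -0.54). In the thick limb, uromodulin Umod (-0.95 ± 0.31) and claudin Cldn10 (-1.03 ± 0.17) were lower. The sodium pump regulator Fxyd2 was lower (-0.61 ± 0.15) and the kinase gene Wnk4, which controls the thiazide-sensitive cotransporter, higher (0.42 ± 0.09).

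On the higher side, extracellular matrix and fibrosis had 26 of 29 genes (median 0.77; camera adjusted p = 2.95e-13, and adjusted p = 0.405 with an estimated correlation), with thrombospondin Thbs1 (1.24 ± 0.14) and collagen Col5a2 (0.83 ± 0.13). Mural and renin cell markers had 6 of 11 higher, with the pericyte receptor Pdgfrb (0.82 ± 0.13) and smooth muscle actin Acta2 (0.82 ± 0.19). Macrophages and neutrophils had 15 of 21 higher (17 when adjusted over the list alone; median 0.63), with C1qb (1.0 ± 0.16) and Cd68 (0.74 ± 0.13), and Gpnmb, a macrophage and injury gene, at 1.77 ± 0.34. Tubular injury had 10 of 21 higher (12 when adjusted over the list alone; median 0.59; camera adjusted p = 0.000337, and adjusted p = 0.61 with an estimated correlation), with Havcr1 at 113 ± 41.3 against 36.4 ± 22.6 FPKM, Clu (1.48 ± 0.34) and Vim (1.11 ± 0.23). Immediate early genes had 11 of 21 higher, with Myc (1.17 ± 0.21) and Klf6 (1.06 ± 0.18). Interferon response had 9 of 24 higher. The cytokine Il24 (1.95 ± 0.40), the vitamin D catabolic enzyme gene Cyp24a1 (1.61 ± 0.41) and endothelin-1 Edn1 (0.88 ± 0.19) were higher as well.

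In all 4445 of 14899 genes passed at 2pm on high salt, 2112 higher and 2333 lower, 351 of them by over 2 fold (139 higher, 212 lower). The libraries come from 2 number series with both genotypes in each, and the series differ. Within each series the label Per1KO and SS have separate number ranges, adjoining in the earlier and apart in the later. Neither series parts the label from library number. The earlier series holds Per1KO replicates 1 to 3 and SS replicates 1 and 2, the later Per1KO replicates 4 and 5 and SS replicates 3 to 5. Of the SS libraries, replicates 4 and 5 of the later series stood low in proximal tubule markers (mean log2 7.21 and 7.85) and podocyte markers (1.88 and 2.55) and high in thick ascending limb markers (6.14 and 5.87). Fitted by series, 4581 genes passed in the earlier series and 1499 in the later, and with series as a covariate 2175. Across genes the differences of the series correlated at r = 0.31 and rho = 0.35 (14276 genes, not independent replicates), with 676 passing in both in the same direction, 47 opposite and 242.7 the same way by chance. Oxidative phosphorylation was lower in both (38 and 19 genes, medians -0.54 and -0.44) and extracellular matrix higher in both (18 and 14 genes, medians 0.68 and 0.72). The tricarboxylic acid cycle was lower in both but less so in the later (21 and 6 genes, medians -0.70 and -0.22), as was amino acid metabolism (21 and 9 genes, medians -0.67 and -0.29). The proximal tubule transport median turned from -1.12 in the earlier series to 0.43 in the later, that of proximal tubule markers went from -1.34 (13 of 15 lower) to -0.17 (1 lower), and that of fatty acid oxidation from -0.51 to -0.02. Tubular injury had 16 genes higher against none (medians 1.40 and 0.40), macrophages and neutrophils 12 against 1 (0.81 and 0.52), immediate early genes 18 against 1 (1.08 and 0.20), interferon response 9 against 1 (0.50 and 0.21), and mural and renin cell markers 4 against 2 (0.88 and 0.44). No mitochondrially encoded mRNA passed in either. Each series holds 5 of the 10 libraries. The clock gene Arntl turned from log2 1.31 to -1.39, and Dbp from -1.92 to 1.43 (-0.31 and 0.03 in the full fit). In the later series alone Havcr1 (log2 1.08), Clu (0.77), Vim (0.64), Cd68 (0.55), Gpnmb (1.61), Il24 (1.39), Myc (0.85), Edn1 (0.53), Acta2 (0.63), Lrp2 (-0.32), Fxyd2 (-0.53) and Wnk4 (0.36) kept their direction but did not pass, nor did Cyp2c11 (-2.55). In the earlier series alone Rgn (-1.93) and Cyp24a1 (1.12) did not pass. Slc7a12, Slc7a13 and Umod passed in neither, nor in fits without Per1KO replicate 3, without SS replicate 4 or of only the 2pm groups. In all they lost their calls under 7, 12 and 8 settings, for Slc7a13 and Umod also with series as a covariate. Without the filter Fxyd2 did not pass. A fit of only the 2pm groups gave 2641 genes.

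At 2am on high salt, injury mRNA was higher in the label Per1KO, and respiratory chain and sterol synthesis mRNA were lower. Spp1 was 4310 ± 1360 FPKM in the label Per1KO against 1090 ± 789 in SS (log2 2.35 ± 0.58, adjusted p = 0.0173; n = 5 each), Lcn2 72.0 ± 19.2 against 16.7 ± 11.7, Havcr1 89.8 ± 29.5 against 24.6 ± 19.3, and Clu 542 ± 156 against 166 ± 80.3. Tubular injury had 10 of 21 higher (16 when adjusted over the list alone; median 1.11; camera adjusted p = 1.54e-09, and adjusted p = 0.22 with an estimated correlation), Vim included (1.14 ± 0.23). Extracellular matrix had 14 of 29 higher, with Tgfb1 (0.60 ± 0.12) and Lox (0.94 ± 0.21). Macrophages and neutrophils had 10 of 21 higher, with the mannose receptor Mrc1 (1.08 ± 0.19) and C1qb (0.76 ± 0.16), beside Gpnmb (2.02 ± 0.34) and complement C4b (2.06 ± 0.47). Interferon response had 10 of 24 higher (13 when adjusted over the list alone), with the guanylate-binding Gbp2 (1.04 ± 0.22) and Oasl (0.76 ± 0.14). Edn1 was higher (0.91 ± 0.19), as were Angptl4 (1.93 ± 0.47) and the branched-chain transaminase gene Bcat1 (1.05 ± 0.23).

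Oxidative phosphorylation at 2am on high salt had 40 of 48 lower and none higher (45 lower when adjusted over the list alone; median -0.44; camera adjusted p = 1.61e-33, and adjusted p = 0.149 with an estimated correlation), with the complex I subunit Ndufs3 (-0.52 ± 0.07) and the ATP synthase subunit Atp5c1 (-0.45 ± 0.07). The tricarboxylic acid cycle had 15 of 21 lower, with Sdhd (-0.51 ± 0.07) and Mdh2 (-0.48 ± 0.08). Cholesterol synthesis and uptake had 7 of 21 lower (16 when adjusted over the list alone; median -0.43), with Insig1 (-0.80 ± 0.14) and Msmo1 (-0.63 ± 0.13), and glycolysis 6 of 18 lower, with Gpi (-0.40 ± 0.08) and Eno1 (-0.53 ± 0.13). Fxyd2 was lower (-0.60 ± 0.15). Large falls were Mff, a mitochondrial fission factor gene (-2.18 ± 0.46), Ces1d (-1.43 ± 0.30), the nuclease Dnase1 (-1.41 ± 0.26), Ddit4l2 (-1.39 ± 0.33) and Ppard (-1.18 ± 0.21). In all 1333 genes passed, 641 higher and 692 lower, and of 108 that differed by over 2 fold 98 were higher. Proximal tubule markers had 1 of 15 lower (median -0.49), their mean score differing by -0.52 ± 0.13 SE. SS replicate 1 had a low tubular injury score (mean log2 3.65, others 4.29 to 4.99), and without it 492 genes passed and Lcn2, Spp1 and Angptl4 did not. Without SS replicate 5 Spp1, Angptl4 and Ddit4l2 did not pass, without Per1KO replicate 4 Angptl4, Eno1 and Fxyd2 did not, without Per1KO replicate 2 Angptl4 did not, and without the filter Fxyd2 did not. The highest count was 1854 without Per1KO replicate 1, 6 of 10 libraries moved the count by over 1.5 times, and a fit of only these groups gave 2369.

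Some label differences recur between comparisons. Across genes the normal and high salt differences at 2am correlated at r = 0.63 and rho = 0.63 (13260 genes, not independent replicates), and 279 genes passed in both with the same direction, none with the opposite and 25.5 by chance. Ces1d, Ddit4l2 and Ppard were lower and Lcn2, Spp1, Havcr1 and Clu higher in both. At 2am the libraries of the label Per1KO and of SS have separate number ranges on both diets, so the design does not part the label from library series in these differences or in what the diets share. The 2pm and 2am differences on high salt shared 971 genes in direction and 7 in opposition, with 199.2 by chance (r = 0.52). At 2pm the 2 diets shared 11 genes, with 7.5 by chance (r = 0.10).

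In SS rats on high salt, clock genes again moved strongly between 2pm and 2am, with wide scatter at 2pm. Nr1d1 fell from 26.4 ± 8.01 to 1.82 ± 0.546 FPKM (log2 -3.24 ± 0.19, adjusted p = 8.88e-09), Nr1d2 by 1.95 ± 0.23, and Cry1 rose by 2.05 ± 0.25 and Arntl by 1.79 ± 0.44. Dbp, at -1.11 ± 0.55 (adjusted p = 0.211), did not pass: its 2pm level was 80.0 ± 82.4 FPKM. SS 2pm replicates 3 to 5 held 2.66 to 3.87 FPKM of Per2, outside both the 20.8 to 22.9 of replicates 1 and 2 and the 16.7 to 22.3 of the 2am libraries. Core clock had 4 of 17 higher and 2 lower. Rises included Slc16a1 (2.69 ± 0.47), the glycine cleavage enzyme gene Gldc (2.42 ± 0.68), Ddit4l2 (2.13 ± 0.33), the peptide transporter Slc15a1 (1.95 ± 0.40), Barx2 (1.92 ± 0.27), the magnesium channel Trpm6 (0.73 ± 0.12), endoglin Eng (0.66 ± 0.14) and Sgk1 (0.83 ± 0.20). Falls included the guanylate cyclase subunit Gucy1b2 (-2.0 ± 0.49), Cldn3 (-1.94 ± 0.48) and Stc1 (-1.72 ± 0.38). Collecting duct principal cell markers had 3 of 10 lower (7 when adjusted over the list alone; camera adjusted p = 0.000288, and adjusted p = 0.601 with an estimated correlation), with the water channels Aqp2 (-1.08 ± 0.30) and Aqp3 (-0.74 ± 0.17). The tricarboxylic acid cycle had 5 of 21 higher, with Idh2 (0.56 ± 0.14), cholesterol synthesis 3 of 21, with Insig1 (0.74 ± 0.14), and the heat shock list 4 of 19, with Fkbp4 (0.87 ± 0.13).

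In all 811 of 14899 genes changed with time in SS on high salt, 425 up and 386 down. The SS time differences on the 2 diets correlated across genes at r = 0.56 and rho = 0.53, with 421 genes shared in direction, 3 opposite and 100.3 by chance. The 811 depends on the libraries of 2pm: 233 passed with the earlier series alone, 3502 with the later series alone, 170 without SS 2pm replicates 4 and 5, and 47 in a fit of only these groups. In the earlier series Aqp2, Aqp3, Stc1, Cldn3, Gldc, Slc15a1, Gucy1b2, Idh2, Sgk1, Eng and Trpm6 did not pass. In a fit of only these groups all of these but Trpm6 lost their call, as did Slc16a1, Ddit4l2 and Arntl. Without SS 2pm replicate 4 Gldc, Aqp2, Aqp3, Gucy1b2, Cldn3, Idh2 and Sgk1 did not pass, and without SS 2am replicate 1 the same genes except Aqp3, and Arntl, did not. Single libraries moved it from 346 (without SS 2am replicate 1) to 2401 (without SS 2pm replicate 1), beyond 1.5 times for 7 of 10.

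In the label Per1KO on high salt few genes changed between the times. The largest rises were Csmd1 (1.10 ± 0.19), Pzp, a protease inhibitor gene (1.07 ± 0.18), Ehhadh (0.96 ± 0.20), Ndrg1 (0.93 ± 0.15), the transcription factor Tfec (0.74 ± 0.11) and Entpd5 (0.71 ± 0.14). Slc17a3 (0.68 ± 0.12) and Etfa (0.39 ± 0.08) rose as well. Falls included Prg4 (-0.77 ± 0.13), the intercalated cell proton pump subunit Atp6v1g3 (-0.75 ± 0.14), the ceramidase Acer2 (-0.67 ± 0.12), the glycolytic regulator Pfkfb3 (-0.58 ± 0.10) and Sh3d21 (-0.56 ± 0.09). Nr1d1 at 12.7 ± 1.99 and 6.62 ± 0.793 FPKM (-0.84 ± 0.19, adjusted p = 0.0552) did not pass, nor did any other core clock gene. In all 39 genes passed, 27 up and 12 down. As a list the tricarboxylic acid cycle had none of 21 past the threshold but 17 higher when adjusted over the list alone (camera adjusted p = 2.1e-12, and adjusted p = 0.211 with an estimated correlation). Fatty acid oxidation had 2 of 36 higher (12 when adjusted over the list alone). Oxidative stress and NADPH oxidase genes, 1 of 25 higher, kept their call with an estimated correlation (camera adjusted p = 0.000253, and adjusted p = 0.0375 with an estimated correlation).

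This count is fragile. It ran from 3 without Per1KO 2am replicate 5 to 240 without Per1KO 2pm replicate 4, beyond 1.5 times for all 10 libraries, and was 5 with replicate number as a block, 14 without the filter, 119 with voom, 674 in a fit of only these groups, 1313 with the earlier series of 2pm and 1 with the later, in which none of the genes named above passed. Of those genes only Tfec passed in every leave-one-out fit. The time differences of the label Per1KO on normal and high salt correlated across genes at r = -0.06 and rho = -0.14.

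The test of damping on high salt passed for 15 of 14899 genes, 7 positive and 8 negative. Nr1d1 was the only core clock gene (2.40 ± 0.27, adjusted p = 0.000487), although 16 of 17 core clock genes had a smaller time difference in the label Per1KO (median absolute log2 0.37 against 0.78). Hpdl, a dioxygenase-like gene, differed by 1.52 ± 0.27, Creb3l1, a stress-activated transcription factor gene, by -1.28 ± 0.22, and Eng by -1.10 ± 0.20. These 3 did not pass under 17, 14 and 18 settings. All 3 failed without the filter, with the later series, without SS 2pm replicates 4 and 5, and without any 1 of Per1KO 2pm replicates 1 and 3, Per1KO 2am replicates 2 to 5, SS 2pm replicate 2 or SS 2am replicates 1, 2, 3 and 5. The count was 8 without the filter, 8 with replicate number as a block, 473 with the earlier series of 2pm, 8 with the later and 4 without SS 2pm replicates 4 and 5. Single libraries took it to between 1 and 165, the latter without SS high salt 2pm replicate 1, and 15 of 20 moved it by over 1.5 times.

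**Figure D3:**
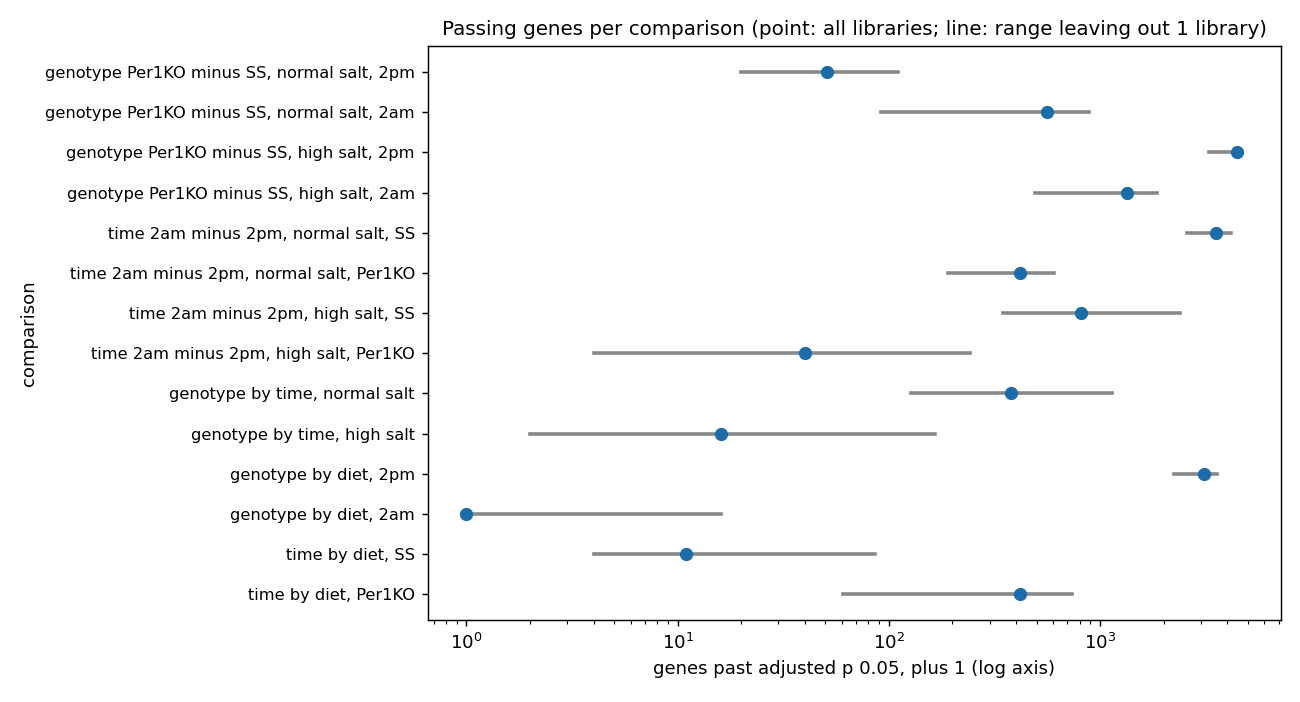
Genes past an adjusted p of 0.05 in each of 14 comparisons, on a log axis with 1 added; the point is the full fit and the line spans the fits that leave out 1 library at a time. The count for time in the label Per1KO on high salt runs from 3 to 240 around 39, and that for the label at 2pm on high salt from 3285 to 4681 around 4445.

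Whether diet changed the label difference was tested in a joint fit of all 43 libraries. The label is not parted from library number series in the normal salt arm at 2pm or in either arm at 2am. A series difference within an arm does not cancel in this test. At 2pm, 3102 of 14102 genes differed, 1548 upward and 1554 downward on high relative to normal salt. Il24 (2.08 ± 0.49), Vim (1.31 ± 0.28) and Tgfb1 (0.93 ± 0.18) had higher label differences on high salt. Cycs (-1.12 ± 0.19), Lrp2 (-1.17 ± 0.26), the creatine synthesis enzyme gene Gatm (-1.79 ± 0.59) and Kap, an androgen-regulated kidney gene (-1.79 ± 0.50), had lower ones. Cycs stood at 604 ± 83.0 and 659 ± 120 FPKM in the label Per1KO and SS on normal salt, against 352 ± 71.9 and 828 ± 156 on high salt. Oxidative phosphorylation had 27 of 48 lower (32 when adjusted over the list alone; camera adjusted p = 3.57e-12, and adjusted p = 0.555 with an estimated correlation), the tricarboxylic acid cycle 15 of 21 and fatty acid oxidation 12 of 36. Extracellular matrix had 21 of 29 higher (24 when adjusted over the list alone; median 0.82), macrophages and neutrophils 13 of 21 and tubular injury 7 of 21. Proximal tubule markers had 6 of 15 lower. The earlier high salt 2pm series alone gave 4446 genes and the later 537, Cycs being the only gene named here that passed in the later. Gatm did not pass without any 1 of Per1KO high salt 2pm replicates 2 and 3 or SS high salt 2pm replicates 1 and 2.

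At 2am no gene passed for diet by label with limma or with voom, and 821 of 14102 had an unadjusted p under 0.05 (smallest adjusted p = 0.229). Cholesterol synthesis and uptake was lower as a list, and its call held with an estimated correlation (camera adjusted p = 1.05e-16, and adjusted p = 0.00225 with an estimated correlation). Of its 21 genes 7 were lower when adjusted over the list alone, and none over all genes, where Insig1 at -0.79 ± 0.16 had an adjusted p of 0.229. Insig1, a brake on sterol synthesis that sterol-regulated transcription itself drives, stood at 21.8 ± 4.33 and 38.6 ± 5.99 FPKM in the label Per1KO and SS on high salt and at 27.7 ± 2.67 and 28.0 ± 2.67 on normal salt. Separate fits of the 2 tables gave 2 genes. Without Per1KO high salt 2am replicate 1, 15 genes passed.

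For time by diet in SS, 10 genes passed, 3 higher and 7 lower, among them Haus4 of the mitotic spindle (0.69 ± 0.13), Klf3 (-0.55 ± 0.11) and Heca (-0.51 ± 0.09). Of 100 groupings of the libraries, the real one included, 11 gave at least as many, so chance is not excluded. In the label Per1KO 415 genes passed, 204 higher and 211 lower. Pzp (1.35 ± 0.23) had a higher time difference on high salt and Scnn1a (-1.13 ± 0.27) and Pdgfrb (-0.94 ± 0.21) lower ones. Fatty acid oxidation had 9 of 36 higher (17 when adjusted over the list alone; camera adjusted p = 2.37e-12, and adjusted p = 0.359 with an estimated correlation), Etfa among them (0.56 ± 0.13), and extracellular matrix 5 of 29 lower. In SS the count was 43 in separate fits, 6 with voom, 127 and 338 with the earlier and later high salt 2pm series, and 5 without SS high salt 2pm replicates 4 and 5, where Klf3 did not pass. Haus4 did not pass without SS high salt 2am replicate 2. In the label Per1KO it was 827 in separate fits, 214 without the filter, and 1328 and 4 with the earlier and later series, no gene named here passing in the later, and without Per1KO high salt 2pm replicate 3 Scnn1a and Etfa did not pass. Single libraries took the SS count from 3 to 85 (without SS normal salt 2pm replicate 5; 9 of 22 beyond 1.5 times), and the other from 60 (without Per1KO high salt 2pm replicate 3) to 739 (without Per1KO normal salt 2pm replicate 4; 14 of 21).

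The diets themselves were processed as separate tables and are set side by side with no test. For 36 of 14102 genes every high salt library stood above every normal salt library in all 4 pairs of groups, and for 36 every one stood below. A single pair of the smallest groups separates one way by chance in 0.4% of genes. That rate bears on the pair by pair counts below and not on separation in all 4 pairs, which chance gives far less often. The largest higher ones were Mt-atp8 (mean log2 0.86), Rps4x (0.60), Myo9a (0.59), Zfp26 (0.48), Rbl1 (0.47), the ceramidase Asah1 (0.40), the cohesin loader Nipbl (0.40) and the mRNA reader Ythdf3 (0.40). The largest lower ones were Mtcp1 (-1.05), RT1-CE10 (-1.03), Asmtl (-0.81), the respiratory subunits Cox8a (-0.81) and Ndufa13 (-0.68), Naa38 (-0.77), Bcl7c (-0.76) and Hyi (-0.74). The higher genes had a median length of 3371.5 bases and the lower ones 949.5, against 2146 over all. Pair by pair, 1566 genes stood above and 1586 below in the label Per1KO at 2pm, 1497 and 1356 at 2am, 537 and 366 in SS at 2pm and 478 and 353 at 2am. The tubular injury median was 1.07 at 2pm and 0.66 at 2am in the label Per1KO and 0.18 and 0.17 in SS. For oxidative phosphorylation it was -0.59 and -0.26 in the label Per1KO and -0.13 and -0.05 in SS. Per1 stood in no separated set (-0.46 and -0.65 in SS, -0.04 and -0.15 in the label Per1KO).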

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

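The library series, the clock state of single libraries and the tissue markers were tested after the results had been seen. The interactions were planned.

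Between the genotypes, time differences differed on normal salt for 378 genes, with log2 2.35 for Nr1d1, -1.97 for Arntl, 1.72 for Dbp, 1.60 for Ciart, 1.32 for Per3, -1.99 for Slc16a1 (lost under 13 settings), -1.87 for Prima1 and -1.61 for Sgk1. On high salt they differed for 15, with 2.40 for Nr1d1, 1.52 for Hpdl, -1.28 for Creb3l1 and -1.10 for Eng (the last 3 lost under 17, 14 and 18 settings). Between the diets, the label difference at 2pm differed for 3102 genes, with 2.08 for Il24, 1.31 for Vim, 0.93 for Tgfb1, -1.12 for Cycs, -1.17 for Lrp2, -1.79 for Gatm and -1.79 for Kap. The time difference differed by diet for 10 genes in SS, with 0.69 for Haus4, -0.51 for Heca and -0.55 for Klf3, and for 415 in the label Per1KO, with 1.35 for Pzp, -1.13 for Scnn1a, -0.94 for Pdgfrb and 0.56 for Etfa.

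Of 218 groups of 5 or 6 libraries tested for a library far from the others, 13 held one, where chance gives 10.9 (4 of 138 for clock genes, 9 of 80 for marker scores). Marker scores held more than their share of that chance number and clock genes fewer. The pooled count therefore does not place the marker scores at chance level. Per2 was 16.7 FPKM in SS high salt 2am replicate 2 (others 21.1 to 22.3), Cry1 4.91 in SS normal salt 2pm replicate 1 (2.27 to 2.96), and Bhlhe40 48.8 in SS normal salt 2am replicate 4 (56.5 to 60.8) and 47.3 in SS high salt 2am replicate 4 (58.6 to 63.8). Proximal tubule markers had a mean log2 of 8.66 in Per1KO normal salt 2am replicate 4 (8.49 to 8.52) and 8.59 in Per1KO high salt 2am replicate 1 (8.18 to 8.28). Thick ascending limb markers had 4.86 in Per1KO high salt 2pm replicate 3 (5.37 to 5.46) and 5.88 in SS high salt 2am replicate 4 (5.20 to 5.25). Distal convoluted tubule markers had 4.30 in Per1KO high salt 2am replicate 1 (4.00 to 4.08) and 2.94 in SS high salt 2pm replicate 4 (4.11 to 4.28). Medulla markers had 2.07 in Per1KO high salt 2pm replicate 1 (2.28 to 2.32), and perirenal fat markers 6.29 in Per1KO normal salt 2pm replicate 1 (3.20 to 3.61) and 4.06 in SS normal salt 2am replicate 3 (3.03 to 3.37).

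In SS high salt 2pm replicates 3 to 5, Arntl was high and Per2, Per3, Cry1 and Dbp low, while Nr1d1 stayed above its 2am level. A shift between the library series that acted alike on both genotypes would give the same move in the label Per1KO. The median ratio of the Per1KO to the SS difference between the series was -0.06. Clock swings were smaller in the label Per1KO, and the later Per1KO and SS libraries have separate number ranges. A shift confined to the later SS libraries, or larger in them, is therefore not excluded. An exchange with the 2am group or a mixture of both times cannot put genes outside both ranges, yet all 3 libraries lay outside them for 4 of 17 clock genes (Per2, Cry1, Cry2 and Hlf). For deeper tissue in the sample, replicates 3 and 5 had medulla scores (1.57 and 1.88) inside the 1.39 to 2.32 of the other 17 high salt libraries. Replicate 4 had 2.92. Replicates 4 and 5 also stood low in proximal tubule markers and high in thick ascending limb markers, so deeper tissue is not excluded for these 2. The medulla score of replicate 3 gives no sign of it. A different hour of collection than the label says may fit and was not tested, since no table holds the hour.

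Per1 mRNA was not lower in libraries labelled Per1KO. Single libraries carrying the other genotype's label would put Nr1d1 inside the other genotype's range at the same time, and 0 of 23 normal salt libraries did so: 30.0 to 44.5 in SS against 14.6 to 21.2 FPKM in Per1KO at 2pm, and 1.37 to 2.52 against 5.88 to 6.79 at 2am. On normal salt the label is not parted from library series, so this gap is not tied to genotype alone. The check was not made on high salt. There SS Nr1d1 reached down to 13.4 FPKM at 2pm, close to the Per1KO mean given above. Reads of an overlapping gene are excluded, since 0 listed genes overlap Per1. An allele that leaves the mRNA in place but alters the protein could give this pattern, and FPKM cannot test it.

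On high salt, lower mitochondrial mRNA came with higher injury and matrix mRNA in the label Per1KO. A smaller share of proximal tubule cells would raise the markers of all other cell types. At 2am all 6 lists of other tubule, podocyte and endothelial markers had lower means, while macrophages were higher (difference over its SE 3.18). The ratio to SE was -3.34 for distal tubule, although its genes went both ways, and -2.59 for intercalated cells. In log2 these 2 differences were -0.25 and -0.16. The library size behind FPKM followed the label on high salt, which lowers Per1KO values relative to plain fragment shares. The sign of differences this small depends on that scaling, so a lower share is not excluded at 2am. At 2pm the lowest other list, thick limb markers, gave -1.71, which does not decide, and the shift of SS replicates 4 and 5 keeps it open. At 2pm 5 of 5 stromal genes were higher (Col1a1 0.65, Col3a1 0.72, Acta2 0.82, Tagln 0.77 and Pdgfrb 0.82). All 5 belong to the matrix list that is part of the pattern, so their rise restates it. It is not a separate test of blood cells as the whole cause. A change within tubule cells might remain and was not tested.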

How the results depend on the processing

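Of 246 named values, 233 passed in the full fits, and 157 of these passed under every setting chosen in advance. None of the 233 turned direction under any setting. The 4735 values under other settings thus hold 0 reversals, but only values that passed in the full fit could be scored as reversed. At 2pm on high salt, Arntl (log2 1.31 and -1.39) and Dbp (-1.92 and 1.43) turned between the earlier and later series. Voom, the single series and the removal of SS high salt 2pm replicates 4 and 5 were chosen after seeing the data. Leave-one-out fits kept 2423 of 2766 calls. Pseudocount and median-ratio rescaling moved no count by over 1.5 times, and rescaling ended no named call. For the counts below the cause was not tested, except that a fit of fewer libraries has fewer degrees of freedom.

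In fits of only the groups compared, label counts were 3 and 2371 on normal salt at 2pm and 2am and 2641 and 2369 on high salt, and time counts were 1785 (SS) and 806 (Per1KO) on normal salt and 47 (SS) and 674 (Per1KO) on high salt. Without the filter, time in Per1KO on high salt gave 14, label by time 181 on normal and 8 on high salt, and time by diet in Per1KO 214. With replicate number as a block (the labels give no pairing), time gave 272 in Per1KO on normal salt and 5 on high salt, and label by time 657 and 8, while the other counts stayed within 1.5 times.

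For label at 2pm on high salt, series as a covariate gave 2175 and the later series alone 1499. Time on high salt gave 233 with the earlier and 3502 with the later series in SS, and 1313 and 1 in Per1KO. Label by time gave 473 and 8, label by diet at 2pm 537 with the later series, and time by diet 127 and 338 in SS and 1328 and 4 in Per1KO. Without SS high salt 2pm replicates 4 and 5, time in SS gave 170, label by time 4 and time by diet in SS 5. Separate fits per table gave 2 for label by diet at 2am, and 43 (SS) and 827 (Per1KO) for time by diet. Voom gave 119 for time in Per1KO on high salt and 6 for time by diet in SS. With an estimated correlation 2 list calls of 194 remained.

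Leaving out 1 library at a time, label counts ran from 19 to 110 and from 91 to 888 on normal salt (2pm, 2am) and from 3285 to 4681 and 492 to 1854 on high salt. Time counts ran from 2581 to 4179 (SS) and 190 to 601 (Per1KO) on normal salt, and from 346 to 2401 and 3 to 240 on high salt. Label by time ran from 127 to 1137 and 1 to 165, label by diet from 2234 to 3579 at 2pm and 0 to 15 at 2am, and time by diet from 3 to 85 (SS) and 60 to 739 (Per1KO).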

Other observations

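On high salt at 2pm, vasoactive and transport genes outside the groups described above moved both ways in the label Per1KO, and all were chosen by the rule for named genes. In the renin-angiotensin and endothelin list 3 of 13 were higher and 4 lower (3 and 4 when adjusted over the list alone): the endothelin-converting enzyme gene Ece1 (0.37 ± 0.07) was higher with Edn1, and Enpep, which degrades angiotensin II (-0.69 ± 0.12), and the prorenin receptor gene Atp6ap2 (-0.39 ± 0.08) were lower. At 2am Ece1 was higher too (0.26 ± 0.07). In the sodium and potassium transport list 3 of 31 were higher and 6 lower at 2pm, with the kinase gene Oxsr1 (0.26 ± 0.07) higher and Cul3, a ligase that degrades WNK kinases (-0.34 ± 0.07), lower. In the later series of 2pm alone Ece1 (0.27), Atp6ap2 (-0.38), Oxsr1 (0.18) and Cul3 (-0.27) did not pass, nor did Oxsr1 with series as a covariate. At 2am 2 of 31 were lower, Fxyd2 and the chloride channel subunit Bsnd (-0.54 ± 0.14). The 2am call for Ece1 ended without any 1 of Per1KO replicates 2 to 5 or SS replicates 1, 3 and 5, and that for Bsnd without any 1 of these except Per1KO replicate 3. Xenobiotic and steroid metabolism had 2 of 22 higher and 7 lower at 2pm, with Cyp2d4 (-0.82 ± 0.14) and the sulfotransferase Sult1b1 (-0.93 ± 0.20) lower, but its median turned from -0.94 in the earlier series to 0.17 in the later (14 and 3 lower).

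Some vascular, glomerular and lymphocyte genes differed on high salt at 2pm, in shares near or below that of all genes (4445 of 14899). Podocyte markers had 3 of 10 higher, with Plce1 (0.50 ± 0.10), where SS replicates 4 and 5 stood low. Endothelial markers had 2 of 12 higher and 1 lower: Eng (0.63 ± 0.14) and the junction cadherin Cdh5 (0.39 ± 0.13) were higher and von Willebrand factor Vwf lower (-0.96 ± 0.18). T and B lymphocytes had 4 of 15 higher, with Cd2 (0.69 ± 0.17) and Cd4 (0.53 ± 0.15). In the later series alone Plce1 (0.47), Eng (0.63), Vwf (-0.62) and Cd2 (0.56) did not pass, and no lymphocyte or endothelial gene of these lists did. The podocyte median was -0.05 in the earlier series and 0.86 in the later, with 1 gene higher in each. Cd4 passed in neither series (adjusted p = 0.0831 and 0.0991), and Cdh5 lost its call under 8 settings, among them each series alone, series as a covariate, a fit of only these groups, and the removal of Per1KO replicate 1 or 5 or SS replicate 5. At 2am on high salt the chaperone genes Fkbp4 (-0.61 ± 0.13) and Hspd1 (-0.41 ± 0.09) were lower and the cold-inducible Rbm3 was higher (0.74 ± 0.19), where in SS chaperones rise at 2am. Rbm3 did not pass without any 1 of Per1KO replicates 2, 4 and 5 or SS replicates 1 and 5. In the label Per1KO on normal salt 3 of 12 endothelial markers rose at 2am, the diaphragm gene Plvap (0.54 ± 0.11), the VEGF receptor Flt1 (0.43 ± 0.10) and the angiopoietin receptor Tek (0.33 ± 0.08). Flt1 and Tek did not pass with replicate number as a block, without any 1 of 2pm replicates 1, 3 and 6, or without 2am replicate 5, nor did Flt1 without 2am replicate 3 or Tek without 2am replicate 1, 2 or 4.

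High salt marker scores differed, label Per1KO minus SS, at 2pm by 0.59 ± 0.08 SE for macrophages, 0.58 ± 0.13 for mural cells, 0.50 ± 0.38 for podocytes, 0.43 ± 0.20 for lymphocytes, -0.36 ± 0.21 for thick limb and -0.56 ± 0.36 for proximal tubule, and at 2am by 0.49 ± 0.15, 0.23 ± 0.14 (mural), -0.25 ± 0.08 (distal tubule) and -0.52 ± 0.13 (proximal tubule).

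Each count was set against 99 other groupings of the same libraries, a test chosen in advance. The number of 100 groupings, the real one included, with at least the real count was 2 for label at 2pm on normal salt (real 50, highest other 814), 1 at 2am (561, 8), 1 at 2pm on high salt (4445, 1623) and 1 at 2am (1333, 1015). For time on normal salt it was 1 in SS (3534, 2125) and 1 in the label Per1KO (418, 1), and on high salt 3 in SS (811, 2180) and 1 in the label Per1KO (39, 1). Label by time gave 1 on normal salt (378, 10) and 4 on high salt (15, 4194), label by diet 1 at 2pm (3102, 2693) and 100 at 2am (0, 1), and time by diet 11 in SS (10, 3568) and 1 in the label Per1KO (415, 67). Chance is therefore not excluded for time by diet in SS. For label by diet at 2am the real count of 0 fixes the 100 in advance, so the test decides nothing. The ranks were not adjusted for the number of comparisons, so chance is not excluded at ranks of 2 to 4 of 100 either. These were label at 2pm on normal salt, time in SS on high salt and label by time on high salt. In each, the highest other count (814, 2180 and 4194) was above the real one (50, 811 and 15). For the remaining comparisons none of the 99 other groupings reached the real count, which argues against chance for each taken alone. The high counts of some other groupings may reflect differences between libraries within groups.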
